A study of Homo sapiens with 4 samples.

How the data were processed

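SUDHL4, a germinal-centre type diffuse large B-cell lymphoma line, was cultured for 24 h at 20% O2 (normoxia) or at 1% O2 (hypoxia). miRNAs were measured in the cells and in the exosome fraction precipitated from the culture medium, which gave 4 groups with 1 sample in each. Per the series design text and the labels' protocols, RNA was reverse transcribed with Megaplex Pools A (version 2.1), the products from exosomes alone were then pre-amplified, and quantitative PCR was run on TaqMan human miRNA array cards. Per the labels' protocols, a synthetic plant miRNA (ath-miR159) was added to each lysate as a spike. Its assay was at 35, not detected, in both cell samples, and at 22.97 and 22.98 in the exosome samples. The medium of SUDHL4 and any serum in it are not given in the sources used here.

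The authors deposited 1 table of threshold cycles (Ct), treated here as a score with no fixed range: a Ct 1 cycle earlier stands for about 2 times more template. The Ct values are not normalized, and per the file headers each column is 1 sample. No value lies above 35, and the value 35 marks an assay that was not detected, as read from the values. The authors also deposited a table of ratios, the fold of hypoxia over normoxia in each compartment, made with Data Assist (version 3.1) per the series design text. That text names RNU6B as the invariant control for cells and the spike for exosomes. No assay of the table carries the name RNU6B; the mean of the 4 mammalian U6 wells was used in its place, as fixed before the data were examined. Folds recomputed from Ct with U6 (cells) and the spike (exosomes) differed from the deposited ratios by at most 0.0188% over 124 miRNAs in cells and 0.0233% over 203 miRNAs in exosomes.

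The table holds 384 assays, of which 377 are miRNA assays; the others are the 4 U6 wells, RNU44, RNU48 and the spike. A miRNA was called detected at a Ct below 35: 140 in normoxic cells, 136 in hypoxic cells, 217 in normoxic exosomes and 212 in hypoxic exosomes. The log2 fold was minus the difference, hypoxia minus normoxia, of Ct relative to the reference, over miRNAs detected in both samples of a compartment (124 in cells, 203 in exosomes). A miRNA detected in 1 sample of a compartment has a bound only, computed against Ct 35. With 1 sample per group there is no replicate check and no test, and miRNAs are not replicates. A fixed rule of size, a log2 fold of 1 or more in either direction (2-fold), was used to count miRNAs as higher or lower. The 4 U6 wells on each cell card give the only repeated measure: their SD was 0.0441 cycles in normoxic cells and 0.121 in hypoxic cells, pooled 0.0910, which gives an SD of 0.129 for the difference of 2 wells. This covers wells of an early assay on 1 card, not cultures, extractions or late cycles.

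Between compartments, log2 folds were centred on their median over the miRNAs detected in all 4 samples, and the exosome minus cell difference was counted at a size of 1. Relative enrichment in exosomes was the median-centred negative Ct in exosomes minus that in cells, counted at a log2 size of 3 (8-fold) at both oxygen levels. Levels were not compared between compartments, since only exosome products were pre-amplified.

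The 22 miRNA lists were fixed before the data were examined: miRNAs linked to hypoxia, to angiogenesis and to B lymphoid cells; the miR-17-92 paralogues, let-7, miR-15/16, miR-29, miR-30, miR-23/27/24, miR-181, miR-99 with miR-125, miR-221 with miR-222, and miR-34 with miR-449 families; the chromosome 19 and chromosome 14 miRNA clusters; and markers of other sources, namely epithelial, erythroid or serum, liver, muscle, neural, myeloid or platelet, and mesenchymal. Members were matched by the number in the assay name, with both arms counted. A list with at least 3 measured members has the percentile of its median log2 fold among 10000 random lists of the same size matched on mean Ct in 5 classes, a description of these samples.

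The named miRNAs followed a rule also fixed beforehand. Per compartment they were miR-210, the 10 largest and 10 smallest log2 folds among miRNAs with a Ct below 32 in both samples, the 3 members with the lowest mean Ct of each list, and the 5 with the lowest Ct among those detected in 1 sample. Between compartments they were the 5 largest and 5 smallest differences and the 5 most enriched and 5 most depleted, all with a Ct below 32 in all 4 samples. Other miRNAs named in the text were chosen after their values were seen.

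Alternatives were other references (median or mean Ct of the miRNAs, RNU44, RNU48, their mean, or none), Ct limits of 32 and 30, size rules of 1.5-fold and 4-fold, undetected assays set to the limit, mean or no centring, and the deposited ratios. The spike in cells and U6 in exosomes were not used as references, since they were at 35 there. A limit above 35 was not run, since it would count undetected assays as measured. Rounding Ct up to whole cycles, leaving out Ct values in the last 0.1 of a cycle, and leaving out miR-323-3p, miR-210 or both were added after the data were examined. Neighbouring miRNA genes were taken from a RefSeq gene table (assembly GRCh38.p14), in which 301 assays matched 1 gene symbol; the arrays name no genome build and no coordinates are given.

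The fold step was tested on simulated Ct values with known changes. In a cell step on 133 miRNAs and an exosome step on 215, 100% of those changed by a log2 size of 2.0 or of 1.5 passed the size rule, and 0% of the unchanged ones did. The simulated noise had the pooled SD of the U6 wells, 0.0910 cycles, far below the size rule, so these rates followed from the setting. They check the arithmetic and give no error rate for real assays, above all at late Ct. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.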

Results

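TaqMan array cards measured miRNAs in SUDHL4 lymphoma cells and in exosomes precipitated from their medium after 24 h at 20% or 1% O2, with 1 sample in each of the 4 groups. No value has a replicate, so no difference below was tested, and each describes these samples. Of the miRNA assays on the card, 37.1% were detected in normoxic cells and 36.1% in hypoxic cells, with median Ct values of 30.9 and 30.9. In the pre-amplified exosome samples 57.6% and 56.2% were detected, with median Ct values of 25.997 and 25.98. Early Ct values were found for miR-19b, of the miR-17-92 cluster known as oncogenic in B-cell lymphoma (21.9 in normoxic cells), for miR-16 (22.7 in normoxic cells) and for miR-20a (14.8 in normoxic exosomes).

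The first comparison asked which cellular miRNAs differ after 24 h of low oxygen. miR-210, the best known hypoxia-induced miRNA, had the largest fold among miRNAs detected in both cell samples. Its Ct moved from 30.9 to 28.5, a log2 fold of 2.72 or 6.58-fold higher than in normoxia. Among miRNAs with a Ct below 32 in both samples, miR-129-3p followed at 3.96-fold and miR-132, a CREB-responsive miRNA, at 2.67-fold. miR-212, whose gene lies within 10 kb of that of miR-132, went the other way. By its bound it was at least 2.92-fold lower in hypoxic cells, from a late Ct of 33.12 in normoxic cells. miR-520e, a member of the chromosome 19 primate-specific cluster, was 2.31 times lower. miR-19a, of the miR-17-92 cluster, had a log2 fold of -0.95, short of the size rule.

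Of the 32.9% of miRNA assays measured in both cell samples, 14 miRNAs were at least 2-fold higher, 4 were at least 2-fold lower and 85.5% of the measured ones lay within 2-fold. Beside miR-210, miR-129-3p and miR-132, the higher ones were miR-128, miR-98, miR-331-5p, miR-483-5p, miR-574-3p, miR-32, miR-145, miR-885-5p, miR-101, miR-652 and miR-193a-5p, with log2 folds from 1.75 for miR-128 to 1.09 for miR-193a-5p. The lower ones were miR-636 at -1.91, miR-323-3p at -1.55, miR-505 at -1.37 and miR-520e at -1.21. Of these 18, 14 had a Ct of 32 or later in at least 1 sample; 3 higher and 1 lower remained among the 88 miRNAs below that limit in both. Next in order below Ct 32 were miR-130b at 0.98, miR-339-3p at 0.91, miR-324-3p at 0.87, miR-423-5p at 0.85, miR-181a at 0.85, miR-296-5p at 0.82 and miR-339-5p at 0.74. At the low end were miR-335 at -0.58, miR-328 at -0.54, miR-146b-5p at -0.47, miR-140-3p at -0.40, miR-422a at -0.32, miR-15a at -0.30, miR-21 at -0.26 and let-7a at -0.21. With RNU44 as the reference, miR-15a, miR-21 and let-7a lay above 0.

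The cellular folds as a whole lay above 0 against U6. Their median was 0.34 (quartiles 0.09 and 0.67), with 96 miRNAs above 0 and 28 below, and the raw Ct moved by a median of -0.0034. U6 came 0.33 cycles later in the hypoxic cells, RNU44 came 0.64 later and RNU48 0.23 later. The split into 14 higher and 4 lower was 7 and 13 with the median Ct of the miRNAs as the reference, 10 and 8 with their mean, 11 and 8 with none, 12 and 6 with RNU48, and 30 and 3 with RNU44. miR-210 stayed between 2.17 and 3.03 over these references. The median and mean Ct of the miRNAs remove a shift that the miRNAs share, so the splits under them could not test such a shift.

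Several miRNAs were detected in 1 of the cell samples. miR-34a, a p53 target, had a Ct of 31.97 in hypoxic cells, at least 10.3-fold higher than the detection limit allows in normoxia, and miR-208b was at least 7.82-fold higher. miR-373 was at least 4.45-fold lower and miR-219-5p at least 3.69-fold lower in hypoxic cells. miR-127-3p had a Ct of 8.61 in normoxic cells, 13.3 cycles before the next miRNA and earlier than any U6 well. It was not detected in hypoxic cells, so no fold is given for it. The authors' deposited ratio for it in cells rounds to 0.0000.

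**Figure D1:**
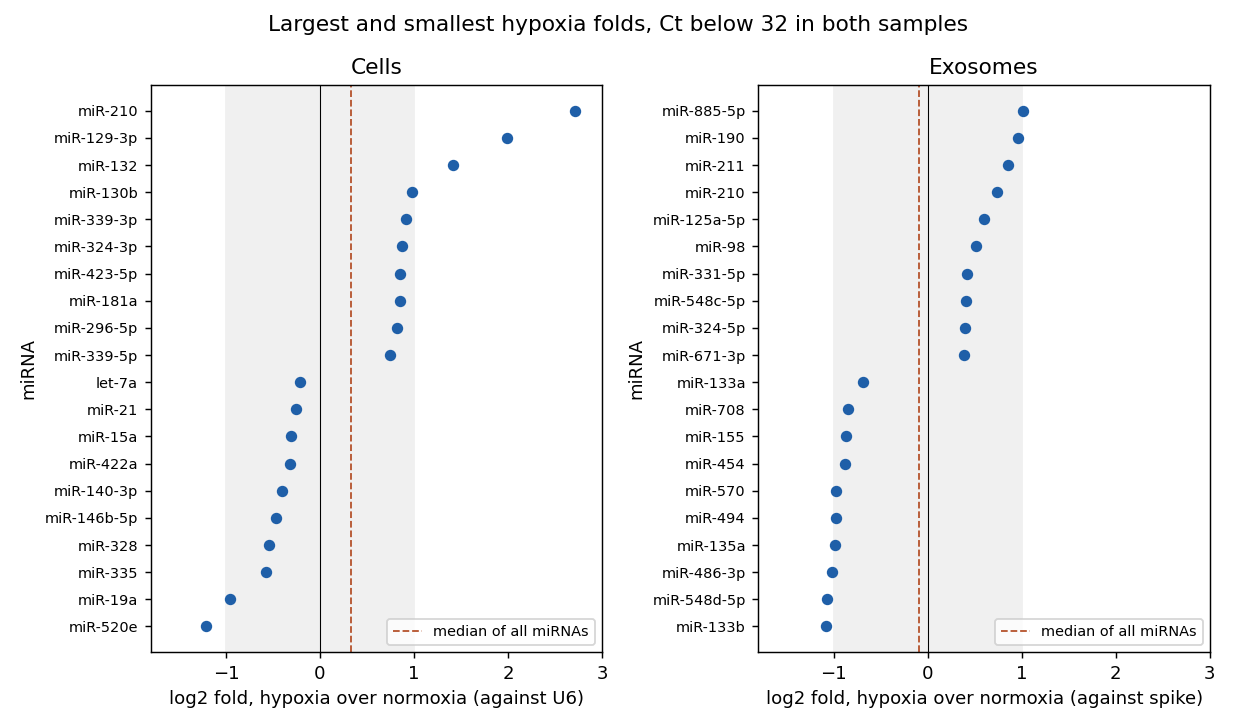
Points show the log2 fold of hypoxia over normoxia for the 10 largest and 10 smallest values among miRNAs with a Ct below 32 in both samples, in cells (left, against U6) and exosomes (right, against the spike). Grey marks less than 2-fold and the dashed line the median of all miRNAs, at 0.34 in cells and -0.09 in exosomes; miR-210 stands apart in cells at 2.72.

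The second comparison asked the same of the exosomes. Here miR-210 was 1.67-fold higher after hypoxia (Ct 22.98 to 22.24), a log2 fold of 0.74, which is short of the size rule. Below Ct 32 in both samples, only miR-885-5p was at least 2-fold higher, at 2.03-fold. The muscle-enriched miR-133b was 2.11 times lower and miR-486-3p 2.03 times lower, and miR-548d-5p lay between them. miR-155, an oncogenic miRNA of activated B cells, had a log2 fold of -0.87.

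Of the 53.8% of assays measured in both exosome samples, 6 miRNAs were at least 2-fold higher, 8 were lower and 189 lay within 2-fold. The higher ones were miR-323-3p at 2.60, miR-375 at 1.77, then miR-146b-3p and miR-202, miR-199a-5p at 1.48 and miR-885-5p at 1.02. The lower ones were miR-96 at -2.79 with a Ct of 34.80 in hypoxia, close to the limit, miR-519a at -2.52, miR-222 at -1.85, miR-618 at -1.43, miR-133b at -1.08, miR-196b at -1.07, miR-548d-5p at -1.07 and miR-486-3p at -1.02. Of these 14, 10 had a Ct of 32 or later in at least 1 sample. With the mean Ct of the miRNAs as the reference the split was 9 higher and 4 lower. The median log2 fold was -0.09 (quartiles -0.31 and 0.10), and the spike differed by 0.0097 cycles. Other values below Ct 32 were miR-190 at 0.96, miR-211 at 0.85, miR-125a-5p at 0.60, miR-98 at 0.51, miR-331-5p at 0.42, miR-548c-5p at 0.41, miR-324-5p at 0.39 and miR-671-3p at 0.39. At the low end were miR-135a, miR-494 and miR-570 at -0.98, miR-454 at -0.88, miR-708 at -0.84 and miR-133a at -0.69.

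Some exosomal miRNAs were detected at 1 oxygen level. miR-215 had a Ct of 25.02 and miR-23a a Ct of 26.9 in exosomes of hypoxic cells and neither was detected in those of normoxic cells, bounds of at least 1019-fold and 272-fold higher. miR-499-5p was at least 16.2-fold higher. The liver miRNA miR-122 was at least 15.8-fold lower, and miR-576-5p at least 8.31-fold lower. Each rests on 1 well.

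The third comparison set the hypoxia folds of the compartments side by side, as the study's title asks for the dynamics inside and outside the cell. miR-885-5p, at a Ct of 34.98 in normoxic cells, was the only miRNA at least 2-fold higher in both among those detected in all 4 samples, and none of these was at least 2-fold lower in both. By bounds, miR-509-5p was at least 2.49-fold higher in cells and 7.44-fold in exosomes, and miR-487a at least 3.18-fold and 7.87-fold lower. miR-323-3p was lower in cells and higher in exosomes, with late Ct values of 33.99 in hypoxic cells and 34.001 in normoxic exosomes. After centring, miR-210 was 1.56 log2 units lower in its exosome fold than in its cell fold, miR-129-3p 1.47 lower, miR-494 1.25 lower, miR-132 1.00 lower and let-7d 0.67 lower. miR-19a had the larger value in exosomes by 1.65, miR-328 by 1.24, miR-335 by 1.17, miR-520e by 1.07 and miR-422a by 0.76. In all, 20 miRNAs differed at least 2-fold between the compartments, 9 with a higher and 11 with a lower exosome value. Fewer did at a Ct limit of 32, where fewer miRNAs entered. Across the miRNAs detected in all 4 samples, which are not independent replicates, folds had a Pearson r of 0.0070 and a Spearman rho of 0.20. Leaving out single miRNAs after their values were seen gave an r of 0.21 without miR-323-3p, -0.056 without miR-210 and 0.14 without both. Among the 88 miRNAs with a Ct below 32 throughout r was 0.31. Centred folds had an SD of 0.68 in cells and 0.40 in exosomes. Ct values were later in cells, where 39.4% of miRNAs with a mean Ct of 32 or more passed the size rule and 5.49% of those below. The SDs therefore do not show a larger response in cells.

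**Figure D2:**
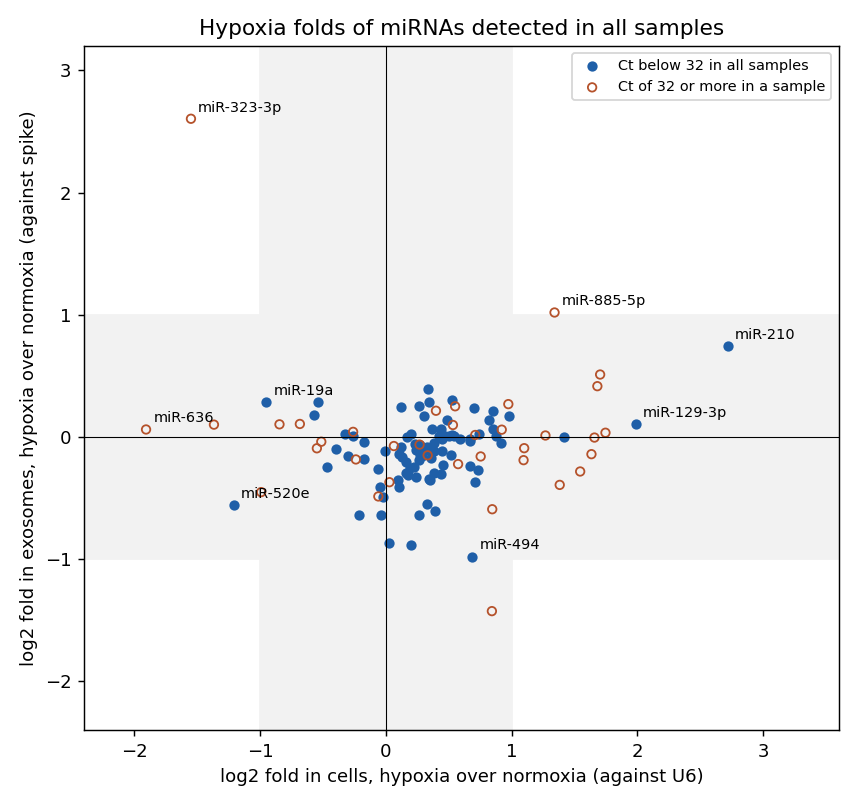
Each point is a miRNA detected in all 4 samples, with its log2 fold of hypoxia over normoxia in cells on the horizontal axis and in exosomes on the vertical axis. Filled points have a Ct below 32 in every sample and grey marks less than 2-fold; miR-323-3p (-1.55 and 2.60) and miR-210 (2.72 and 0.74) lie far from the rest.

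The fourth comparison asked which miRNAs exosomes hold out of proportion to cells. Across miRNAs, Ct values in cells and exosomes had a Pearson r of 0.88 in normoxia and 0.89 in hypoxia, with the same assays in both. Among miRNAs detected in all 4 samples, miR-20b was the only one enriched at least 8-fold in exosomes at both oxygen levels, by 4.29 log2 units in normoxia and 4.72 in hypoxia. Its sequence is close to that of miR-20a and the assays may not fully part them, so this value is uncertain, as are those of miR-17 and miR-106a, miR-18a and miR-18b, miR-19a and miR-19b, and let-7 members. Among miRNAs with a Ct below 32 in all 4 samples, next came miR-20a at a mean of 1.68, miR-195 at 1.66, miR-25 at 1.58 and miR-150 at 1.56. The depleted ones were 7, among them miR-494 at a mean of -6.11, miR-422a at -4.74 and the erythroid miR-486-5p at -4.37; miR-19a at -2.95 and miR-140-3p at -2.71 fell short of the rule. The exosome samples held 61 miRNAs, detected in both, that neither cell sample showed. No miRNA was detected in both cell samples and missing from an exosome sample. Exosome Ct minus cell Ct had a median of -7.54 cycles in normoxia and -7.53 in hypoxia. With such an offset, a miRNA with a late Ct in exosomes would pass the detection limit in cells at an equal proportion. Some of the 61 were earlier in exosomes than the median offset alone accounts for, such as miR-22 at 25.01 in normoxia and 24.66 in hypoxia. The offset also varied between miRNAs: enrichment averaged over both oxygen levels had an SD of 1.70 log2 units. Neither count therefore shows on its own that exosomes hold a selected set of miRNAs. The labels do not settle the medium of SUDHL4 or whether it held serum, so miRNAs from the medium were not excluded from the exosome values, those of the markers of other sources included. Pre-amplification precedes the exosome cards, so these are orders within a sample and not amounts. Any pre-amplification that differs between assays would enter each enrichment value at both oxygen levels. It was not separated from enrichment or depletion here.

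Among 15 measured hypoxia-linked miRNAs in cells, 1 was at least 2-fold higher (miR-210) and 14 lay within 2-fold. Their median of 0.34 was at the 69.9 percentile of random lists, with miR-106a at 0.24, miR-30b at 0.19 and miR-21 at -0.26; by bounds, miR-107 was at least 2.53-fold higher and miR-373 at least 4.45-fold lower. In exosomes all 19 measured members lay within 2-fold (median -0.15, percentile 33.4), such as miR-106a at -0.10, miR-181a at 0.21 and miR-93 at -0.35; miR-23a, detected after hypoxia alone, was at least 272-fold higher. Of the angiogenesis-linked miRNAs, 2 of 13 were at least 2-fold higher in cells, miR-210 and miR-132 (median 0.26, percentile 29.1). In exosomes 1 of 18 was lower, miR-222 (median -0.16, percentile 21.96).

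The B-lymphoid miRNAs were nearly all detected. In cells all 21 measured lay within 2-fold (median 0.23, percentile 8.80), such as miR-19b at 0.27, miR-16 at 0.13 and miR-17 at 0.23. In exosomes 21 of 22 did (median -0.07, percentile 65.8), such as miR-20a at -0.15, miR-19b at -0.19 and miR-17 at -0.06; the other was miR-146b-3p. The miR-17-92 paralogues gave 12 of 12 within 2-fold in cells (median 0.25, percentile 26.9) and in exosomes (median -0.12, percentile 47.5). The let-7 family had 1 of 7 members higher in cells, miR-98 (median 0.38, percentile 44.1), with let-7g at 0.33, let-7b at 0.52 and let-7e at 0.38. miR-98 had a Ct of 34.97 in normoxic cells, close to the limit. In exosomes all 8 let-7 members lay within 2-fold with a median of -0.33, at the 0.65 percentile, 0.24 below the median of all miRNAs. With Ct rounded up to whole cycles, a setting added after the data were examined, that gap was 0.0000. Rounding gives the same fold to all miRNAs whose Ct values share a cycle, so it could not test this gap. let-7g was at -0.55, let-7e at -0.29 and let-7b at 0.02.

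Members of the other families measured in both samples lay within 2-fold, except miR-222; by bounds, miR-23a was at least 272-fold higher in exosomes of hypoxic cells and miR-34a at least 10.3-fold higher in hypoxic cells. The miR-15/16 family had medians of 0.15 over 4 members in cells (percentile 17.2) and -0.15 over 5 in exosomes (percentile 37.4), and miR-29 had 0.20 (percentile 32.7) and -0.02 (percentile 59.5) over 3 each. The miR-23/27/24 family had 0.55 over 3 in cells (percentile 68.1) and -0.11 over 4 in exosomes (percentile 54.8). The miR-99 and miR-125 families had 0.19 over 2 in cells and 0.05 over 6 in exosomes (percentile 78.1), and the miR-34 and miR-449 family had -0.28 over 3 in exosomes (percentile 26.2) and none measured in both cell samples. miR-30 had 0.27 and -0.21 and miR-181 had 0.29 and 0.13 in cells and exosomes, over 2 each. In the miR-221 and miR-222 pair the 1 member measured was miR-222 in exosomes, at -1.85. All cell list medians share the upward shift against U6. With the median Ct of the miRNAs as the reference, those of the hypoxia-linked, B-lymphoid and let-7 lists lay below 0, as did the median of all miRNAs in cells. That reference removes a shift shared by the miRNAs, so it could not test the upward shift.

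Of the neural markers, 2 of 4 measured in cells were at least 2-fold higher, miR-128 and miR-129-3p (median 1.01, percentile 98.9), beside miR-9 at 0.28 and miR-124 at -0.04; below Ct 32 the median was 0.28. By its bound, miR-129-5p was at least 2.58-fold higher in cells. In exosomes all 5 lay within 2-fold (median 0.03, percentile 80.8). Of the epithelial markers, 1 of 7 in exosomes was higher, miR-375 (median 0.22, percentile 95.4), and both measured in cells lay within 2-fold (median 0.36). In normoxic exosomes miR-375 had a Ct of 32.98 and miR-203 one of 33.98. The exosomal members below Ct 32 lay from -0.11 for miR-200c to 0.30 for miR-200a, with miR-429 in the middle at -0.0009. The erythroid or serum markers had 1 of 3 lower in exosomes, miR-486-3p (median -0.17, percentile 47.8), and 1 measured in cells, at 0.53, while miR-486-3p was at least 5.01-fold higher there by its bound. The mesenchymal markers had 1 of 4 higher in exosomes, miR-199a-5p (median -0.26, percentile 24.5), while miR-199b-5p was at least 7.82-fold lower by its bound, and 1 in cells, miR-145 at 1.38. The muscle markers measured in both exosome samples were miR-133a and miR-133b, with a median of -0.89; by bounds, miR-499-5p was at least 16.2-fold higher in exosomes and miR-208b at least 7.82-fold higher in cells. The myeloid or platelet markers had -0.25 over 2 in exosomes and 0.52 for 1 in cells, and the liver marker miR-122 was detected in normoxic exosomes alone.

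Of the 35 chromosome 19 cluster assays, 2 were measured in both cell samples (median -0.18) and 5 in both exosome samples (median -0.59, percentile 5.32), of which miR-519a was at least 2-fold lower; by bounds, miR-518f was at least 2.66-fold lower in exosomes, and miR-519d and miR-517c at least 2-fold. Of the 42 chromosome 14 cluster assays, 2 were measured in cells (median -0.43, miR-323-3p lower) and 3 in exosomes (median 0.89, percentile 94.8, miR-323-3p higher). By bounds others were lower: miR-487a at least 7.87-fold and miR-495 at least 4.83-fold in exosomes, and miR-487a at least 3.18-fold in cells, beside miR-127-3p, for which no fold is given. Over the 25 list medians with a percentile, 1 lay below the 5th and 2 above the 95th, where random lists would give 2.5 outside.

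**Figure D3:**
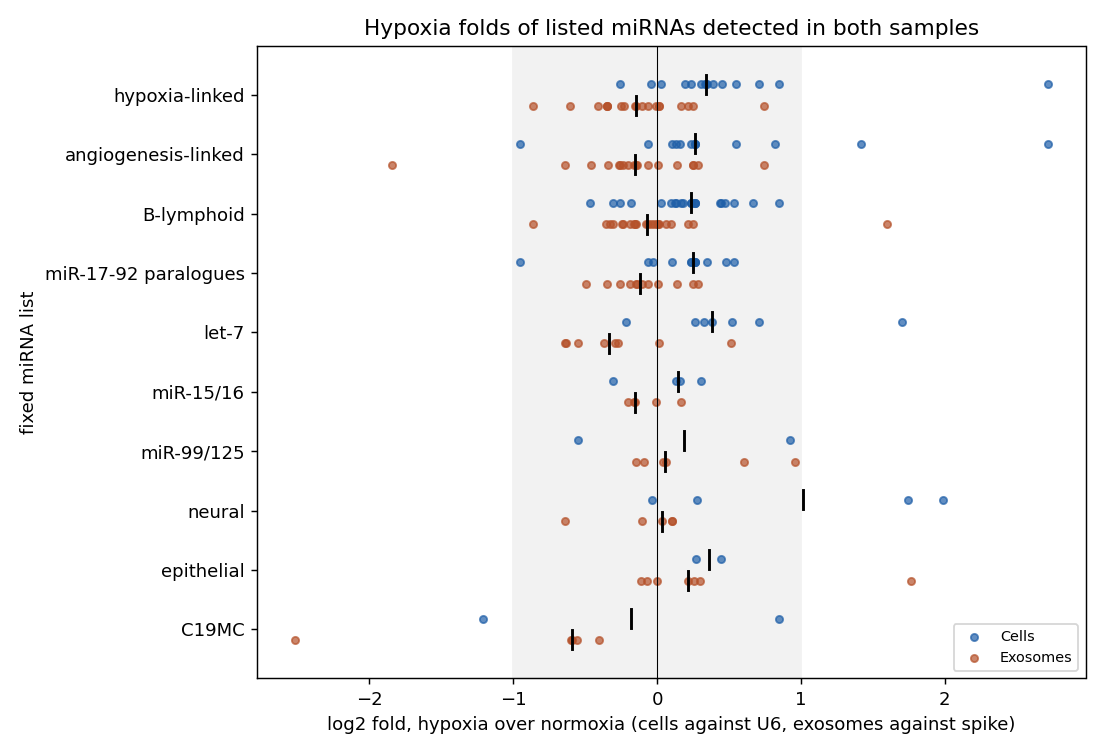
Points are the log2 folds of hypoxia over normoxia of list members detected in both samples, in cells (blue, against U6) and exosomes (orange, against the spike), and black bars are list medians. Grey marks less than 2-fold; most members lie inside it, with miR-210 at 2.72 in cells in the hypoxia-linked and angiogenesis-linked lists.

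Ct values were not spread evenly over the cycle. The last 0.1 of a cycle held 44.5% of Ct values in normoxic cells, 59.2% in hypoxic cells, 49.5% in normoxic exosomes and 61.0% in hypoxic exosomes, against 10% for an even spread. In 91.9% of the miRNAs measured in both cell samples at least 1 of the Ct values lay there, and in 91.1% for exosomes.

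**Figure D4:**
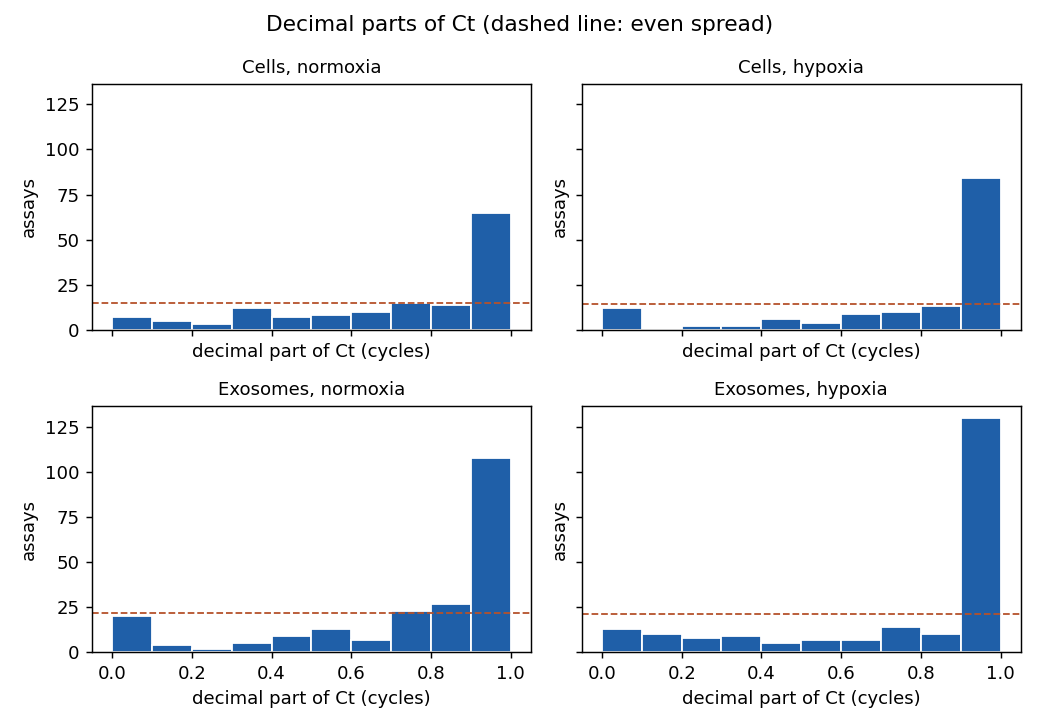
Bars count assays by the decimal part of their Ct, in cycles, in each of the 4 samples, and the dashed line marks an even spread. The last bar holds between 44.5% and 61.0% of the assays of a sample.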

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

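The tests in this part were all chosen after the values were seen. 4 results went opposite ways in cells and exosomes under the same change of oxygen, with 1 sample per group, and none of these differences was tested. The median log2 fold was 0.34 in cells against U6 and -0.092 in exosomes against the spike. The raw Ct in cells moved by a median of -0.0034, so the cell median takes its size from the reference. U6 came 0.33 cycles later, RNU44 0.64 and RNU48 0.23, so each of them puts the cell median above 0. It lay below 0 with the median Ct of the miRNAs as the reference, which removes a shift shared by the miRNAs. miR-323-3p had a log2 fold of -1.55 in cells and 2.60 in exosomes, each resting on 1 well per sample and on late Ct values. Its Ct was 32.104 in normoxic and 33.99 in hypoxic cells. In exosomes it was 34.001 in normoxia and 31.41 in hypoxia. miR-215 was detected in normoxic cells (Ct 33.01) and not in hypoxic cells, and in exosomes of hypoxic cells (Ct 25.02) and not in those of normoxic cells. miR-486-3p was not detected in normoxic cells and at least 5.01-fold higher in hypoxic cells, at a late Ct of 33.01. In exosomes it had a log2 fold of -1.02, just past the size rule.

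The upward shift of cellular miRNAs against U6 may come from the reference as well as from the miRNAs. If U6 alone had come later, RNU44 and RNU48 would have stayed in place. RNU44 came 0.64 cycles later, which goes against a change of U6 alone. RNU48 came 0.23 later, under 2 SDs of a difference of wells (an SD of 0.129). The assays disagree, so they do not decide on a change of U6 alone, which stays open. Less RNA on the hypoxic cell card together with raised miRNAs cannot be told apart from it, since the spike, the assay of known input, was at 35, not detected, in both cell samples although the labels state that each lysate received it. A real rise of miRNAs relative to small nuclear and nucleolar RNAs under hypoxia also stays open, as untested.

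Of the exosome samples, miR-215 and miR-23a were detected in that of hypoxic cells alone. miR-27a is encoded beside miR-23a in the RefSeq gene table (GRCh38.p14), and its exosomal log2 fold was 0.016 against a bound of at least 272-fold for miR-23a, which argues against a change of the whole transcript. For miR-215, its neighbour miR-194 had 0.0094, but miR-194 has another locus that could hold its level, so a change of that transcript stays open. A failed or spurious single well, or a change of these mature miRNAs, stays open for both, as untested.

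The crowding of Ct values just below whole cycles has a candidate source in the choice of threshold. If each Ct had been rounded on its own, miRNAs with neither Ct in the last 0.1 of a cycle would be about as many as for independent samples; they were 10 in cells and 18 in exosomes, at most 0.44 times that number. Pre-amplification is argued against, since the share was at least 44.5% in cells, which had none stated. A threshold per assay placed on 1 of the paired samples within a compartment would remove such miRNAs within compartments and not between them, and between compartments the ratio was at least 1.05. With a shared threshold per assay the Ct differences would not be rounded; no biological explanation was tested.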

How the results depend on the processing

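The settings that round Ct, leave out Ct values in the last 0.1 of a cycle or leave out miR-323-3p, miR-210 or both were chosen after seeing the data; the others were fixed before. miRNAs past the size rule in cells (18) were 33 with RNU44 as the reference and 18 to 22 with the other references. The cell count was 4 at a Ct limit of 32 and 1 at 30; the exosome count (14) was 4 and 0. With a 1.5-fold rule they were 43 and 40, with a 4-fold rule 1 and 3, and with undetected assays set to the limit 34 and 31. Without Ct values in the last 0.1 of a cycle 5 of 10 and 3 of 18 remained to count, since few miRNAs were left. With Ct rounded up, the exosome count was 24. There the spike offset of 0.0097 cycles lets a miRNA whose Ct is 1 whole cycle earlier in hypoxia pass the rule as higher. One whose Ct is 1 cycle later does not pass it as lower. The cell median of 0.34 was -0.22 with the median Ct of the miRNAs as the reference, -0.011 with their mean, 0.65 with RNU44 and 0.0034 with none. RNU48 came 0.23 cycles later in hypoxia, so with it the cell median also lay above 0. The median and mean references come from the miRNAs themselves. They remove a shift that the miRNAs share and could not test it. The median Ct was taken within each sample, so the median fold need not be 0 with it. The correlation between compartments was 0.31 at a limit of 32, 0.18 at 30, 0.21 without miR-323-3p, -0.056 without miR-210 and 0.14 without both. miRNAs differing between compartments (20) were 7 and 3 at these limits, and those enriched or depleted (8) were 4 and 1, since fewer miRNAs entered. Detected miRNAs fell to 91 at 32 and 61 at 30 in normoxic cells and to 62 at 30 in hypoxic cells. Where no construction is given the cause was not tested. Under other references and the deposited ratios, 152 of 506 values of named miRNAs moved by more than the well SD of a difference; a change of reference shifts all of a compartment alike. Over all settings 60 of 217 list medians moved by more than that. The let-7 median in exosomes was 0.24 below that of all miRNAs except with rounded Ct, where it was 0.0000. Rounding removes differences within a cycle, so it could not test this gap. The spike in cells, U6 in exosomes and a limit above 35 gave no values. No paired analysis was possible because each group holds 1 sample. Well error at late Ct was not measured, as the repeated wells are those of U6.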

Other observations

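The tests of neighbouring genes were set before their results were seen, and the shuffle by Ct afterwards. miR-520e had early Ct values, 24.5 in normoxic cells and 18.4 in normoxic exosomes, while 32 of the 35 chromosome 19 cluster assays were detected in neither cell sample and 27 in neither exosome sample. Of the chromosome 14 cluster assays, 38 of 42 were detected in neither cell sample and 36 in neither exosome sample. Of the exosomal neighbours miR-183, miR-96 and miR-182, miR-183 was at -0.06 with a Ct of 24.95 in hypoxia and miR-182 at -0.54 with a Ct of 32.5, and the -2.79 of miR-96 rests on 1 well at a Ct of 34.80. In exosomes miR-125a gave 0.96 and 0.60 from its 3p and 5p assays, at Ct values of 32.01 and 30.98 in hypoxia, while its neighbours let-7e and miR-99b gave -0.29 and 0.06.

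One hypothesis was that neighbouring miRNA genes (within 10 kb) share their hypoxia fold, as a common transcript could give. In cells the 18 measured pairs differed by a median of 0.28 log2 units, at the 2.06 percentile of random sets of pairs (median 0.56). With folds shuffled among miRNAs of like Ct, the same pairs differed by a median of 0.36 and the percentile was 29.8, so closeness of folds may go with abundance, and shared folds stay open. In exosomes the 53 pairs differed by a median of 0.37, at the 67.1 percentile, so no closeness of folds was seen there. The pairs reuse 50 genes and most exosome folds lay within 2-fold, which left little to share, so this does not decide the question.

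Most 2-fold differences had late Ct values, as the counts at a limit of 32 also show. In cells 39.4% of the 33 miRNAs with a mean Ct of 32 or more passed the size rule and 5.49% of the 91 below; in exosomes 40.9% and 2.76% did. Well error at these cycles was not measured. miR-210 in cells, at 6.58-fold, had Ct values below 31.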
